A study of Rattus norvegicus with 36 samples.

How the data were processed

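Nuclei of the hippocampus of 36 rats were sequenced by the submitters with the 10x Chromium 3' v3.1 chemistry on a Illumina NovaSeq instrument, 1 library per animal. The deposited matrices hold raw UMI counts per gene and barcode, which per the labels are the filtered output of Cell Ranger 7.2.0 on the genome build mRatBN7.2. The processing notes also name Seurat and Scanpy without giving them a role, and they state neither the annotation release nor whether intronic reads were counted. The deposited barcode lists and feature lists were used as column and row names only. Groups, sexes, replicate names and library numbers were taken per the labels. The files list 25627 genes, of which 6079 have no symbol and are given by their Ensembl identifier.

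Nuclei with at least 500 detected genes (261356) and at most 5% of UMIs from mitochondrial genes (331 removed) were taken. Doublets were marked per library with Scrublet in scanpy 1.11.5, taking the highest-scoring 0.8% per 1000 barcodes, and 16311 (6.25%) were left out. Mitochondrial genes made 0.0666% to 0.3707% and ribosomal protein genes 0.2465% to 0.5576% of the UMIs of a library. From each library 1500 nuclei were clustered (2000 variable genes, 40 principal components, 20 neighbours, Leiden with leidenalg 0.10.2 and igraph 0.11.9 at resolutions 0.3 and 1), and the other nuclei took the cluster of most of their 15 nearest neighbours (scikit-learn 1.9.0). The 39 clusters at the finer resolution served to find groups of doublets and of blood or mitochondrial transcripts, which were left out. The coarse clusters were named by marker lists fixed before the data were examined, and 4 of them (9, 11, 12 and 18) got no name and entered no class. Class membership by the sum of marker counts, an alternative, matched these names for 50.76% to 77.01% of the nuclei of a library. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

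Counts were summed per library and class, so that the animal is the unit of replication. A library entered a class with at least 20 nuclei, and a class was tested with at least 2 animals of each group and sex, which left 11 classes and 117383 gene-by-class tests. CA1 and CA2 and CA3 nuclei lacked early enrichment F2, microglia and endothelial nuclei lacked late enrichment F1, and committed precursors lacked early stress M3, early enrichment M2 and late enrichment F1. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, glmQLFit with robust dispersion, glmQLFTest) in a model with 1 mean for each of the 12 groups by sex. The comparisons average the sexes, and the sex by treatment tests take the difference between the sexes of each change. P values were adjusted by Benjamini and Hochberg within each class and comparison, with a threshold of 0.05, and every adjusted p of a gene is from edgeR unless another tool is named. The comparisons were tau against GFP, each of the 4 treatments against tau, stress against enrichment at each time, late against early for each treatment, and females against males. Class shares were compared by exact permutation over all splits of 6 against 6 animals, adjusted over 60 tests.

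There were 23 gene lists, fixed before the data were examined: immediate early, glucocorticoid responsive, noradrenergic, tau and tau kinases, interferon response, MHC and antigen presentation, heat shock, unfolded protein response, oxidative phosphorylation, cholesterol synthesis, circadian clock, glutamate receptors and postsynaptic density, synaptic vesicle and release, GABA signalling, neurotrophic and neuropeptide, disease associated microglia, homeostatic microglia, complement, reactive astrocyte, astrocyte homeostasis, myelin, disease associated oligodendrocyte, and immature neuron and neurogenesis. Each was tested with at least 5 measured members in the classes it was meant for by camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over lists and classes within a comparison. Single members were also adjusted over the tests of their list alone. The genes called between tau and GFP served as lists in the direct comparisons of stress and enrichment.

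Named genes were chosen by a rule written before the data were examined. It takes the calls with the largest folds upward and downward with an average log2 CPM above 1 and at least 5 of 6 animals on the same side of the mean of the other group, the strongest members of each list with calls, Mapt, and for the sex tests those with the smallest p. The text names a part of them; some that the rule picks are not reported here. Means and SD are of CPM over animals, and the SE is that of the log2 fold change.

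The alternatives were DESeq2 1.42.0, no TMM, no expression filter, adjustment over all classes together, sex as an additive covariate, the median UMI count of a library as a covariate, a block for the replicate number with and without that covariate, at least 1000 genes per nucleus, marked doublets kept, at least 50 nuclei per library and class, classes by marker sum, only the 12 libraries of the groups compared, each library left out in turn, and for lists an estimated correlation and fry. The p values of fry depend on the basis chosen for the residuals, and so on the linear algebra library: with another kernel of OpenBLAS they shifted while the number of fry calls in each treatment comparison stayed the same, and the run script fixes the kernel. Leaving out early enrichment F2 where it is not compared, leaving out 5 libraries of unusual make-up (early enrichment F2, late enrichment F1 and M3, tau M1, GFP F2) and the ribosomal share as a covariate were added after the data were seen.

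The gene test was tested on simulated data with known changes at the depth of the libraries. In dentate granule nuclei of tau and GFP it called 67.7% of 99 genes changed 1.5-fold and 89% of 100 changed 2-fold, with 11 unchanged genes among 167 calls. In astrocytes it called 32.3% and 72.7%, and in endothelial nuclei 3.2% and 41.9%. An absent call in a class as small as the endothelial one thus says little about changes of 2-fold or less. In astrocytes it says little about changes of 1.5-fold. In early stress and tau it called 74.5% and 86.9% in dentate granule, 45.5% and 92.8% in oligodendrocyte, 34.0% and 72.4% in astrocyte and 3.1% and 25.3% in endothelial nuclei. The list test called the raised and the lowered list of 20 genes in each of 8 runs, and 0 of 100 unchanged lists in each. The simulated genes were drawn independently of each other, so these runs cannot show how the list test behaves for genes that vary together.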

Results

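Single-nucleus RNA sequencing was done on the hippocampus of 36 rats of a TH-Cre line, in which tyrosine hydroxylase neurons carry Cre recombinase. The animals fell into 6 groups of 6, each with 3 females and 3 males, and 1 library was made from each animal. One group received an adeno-associated virus coding for green fluorescent protein (GFP), and the other groups received a virus coding for htauE14, a human tau altered to mimic phosphorylation (tau). Of the tau-injected groups, 1 had no further treatment in the labels, and the others also had early stress, early enrichment, late stress or late enrichment. The study's title names the locus coeruleus, the noradrenergic nucleus that innervates the hippocampus, as the site of the pathology studied.

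The libraries held 274031 barcodes and 1090.6 Mio unique molecular identifiers (UMIs, Mio for 1e6), from 12.262 to 47.317 Mio per library. The mean depth was 32.9 ± 9.75 Mio UMIs (SD, n = 6) in early stress, 28.1 ± 5.86 in early enrichment, 27.0 ± 7.27 in tau, 34.3 ± 10.2 in GFP, 32.0 ± 2.19 in late stress and 27.5 ± 10.7 in late enrichment. After filtering, 244714 nuclei were kept, and the median UMI count per nucleus ran from 1713 to 3896 between libraries. The library numbers in the labels put the 6 libraries of each group in a row, so that a preparation or sequencing batch that followed them would hold 1 group only and no within-batch value could be given.

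Clusters with the fixed markers of 12 cell classes held 213819 nuclei, or 87.38% of those kept. Oligodendrocytes with 59822 nuclei and dentate granule neurons with 58094 nuclei were the most abundant, and committed oligodendrocyte precursors with 1068 and ependymal cells with 335 were the rarest. Microglia made 3.95% ± 0.511 of nuclei (SD, n = 6) in late stress and 1.82% ± 0.943 in tau, and oligodendrocytes made 29.7% ± 3.14 and 19.3% ± 8.84 (2-sided exact permutation p = 0.00216 and 0.00433, adjusted p = 0.0649 and 0.0866, higher in 6 of 6 animals). Ependymal cells made 0.0379% ± 0.0256 in early stress and 0.20% ± 0.135 in tau (exact p = 0.00216, adjusted p = 0.0649). Of the 60 comparisons of a class share with tau or GFP, 5 stood at an unadjusted exact permutation p under 0.05 and 0 passed after adjustment. The exact test could give no p under 0.00216, the value of microglia and ependymal cells, so the absence of a pass says little. With marked doublets kept, 3 passed, with a smallest adjusted p of 0.0433.

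**Figure D1:**
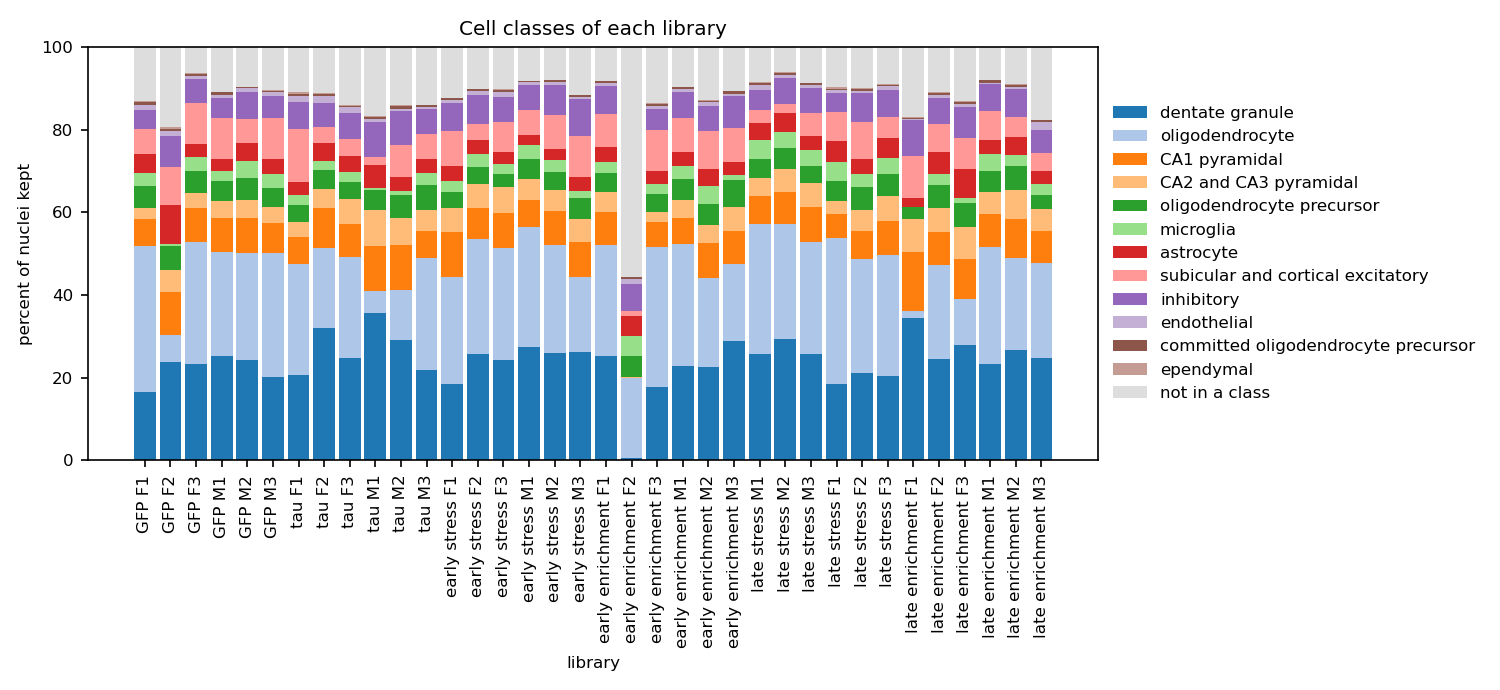
Percent of the nuclei kept (vertical axis) in each cell class (colour) for each library (horizontal axis), with nuclei in no class in grey. The library labelled early enrichment F2 lies at 0.048% CA1 pyramidal nuclei, where the other libraries of its group lie between 6.10% and 8.50%.

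Tau was compared with GFP to ask what the tau virus changed in the hippocampus without stress or enrichment. In the astrocyte class, genes known from oligodendrocytes were higher in tau. Fa2h (ENSRNOG00000018950), an enzyme that makes the hydroxylated fatty acids of myelin lipids, stood at 44.6 ± 19.8 CPM (counts per 1e6 UMIs; SD, n = 6) in tau and 6.27 ± 4.98 in GFP, a log2 fold change of 2.88 ± 0.48 (SE, edgeR adjusted p = 0.00145, higher in 6 of 6 animals). Cntn2, an adhesion molecule of the axon and its myelin, rose by 2.39 ± 0.43 on the log2 scale (adjusted p = 0.00145). Bin1, a membrane-bending protein on the list of tau and its kinases, rose by 0.84 ± 0.19 (adjusted p = 0.0103), the 1 call among the 234 tests of that list, also 1 adjusted over the list alone. The fixed oligodendrocyte markers made 0.174% ± 0.0653 of the UMIs of the astrocyte class in tau and 0.0779% ± 0.0162 in GFP (SD, n = 6, exact permutation p = 0.00433, adjusted p = 0.0108).

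Among neurons, CA1 pyramidal nuclei of tau animals had less Cdh10 and Grm5 transcript. Cdh10 (ENSRNOG00000009771), a cadherin of cell adhesion, stood at 617 ± 170 CPM (SD, n = 6) in tau and 872 ± 116 in GFP, a log2 fold change of -0.54 ± 0.09 (SE, edgeR adjusted p = 0.00363; 0.12 with sex as an additive covariate, 0.158 with a replicate block and 0.178 with classes by marker sum). Grm5 (ENSRNOG00000016429), a metabotropic glutamate receptor, stood at 3551 ± 98.7 and 4375 ± 289 CPM, a log2 fold change of -0.30 ± 0.06 (adjusted p = 0.0135; 0.0612 without tau F3, 0.0516 without the 5 libraries of unusual make-up and 0.308 with classes by marker sum). Of the list of glutamate receptors and postsynaptic density genes, 2 of 150 tests passed, both lower, and 7 did when adjusted over the list alone. Of the list of GABA signalling genes, 2 of 98 passed, both lower, and 11 adjusted over the list alone. Mapt, the rat's own tau gene, had log2 fold changes of 0.02 ± 0.05 in dentate granule and 0.03 ± 0.05 in CA1 pyramidal nuclei (adjusted p = 0.942 and 0.902). Th, Dbh and Slc6a2, genes of noradrenaline synthesis and uptake, had too few counts to be tested in the classes.

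The list of oxidative phosphorylation passed as higher in 4 classes by camera with the preset correlation, and in 0 with an estimated correlation. Of the 26 members, 22 lay higher in tau in oligodendrocyte precursors (median log2 fold change 0.28, limma camera adjusted p = 0.000585), 24 in CA2 and CA3 pyramidal nuclei (0.20, adjusted p = 0.000595), 23 in dentate granule nuclei (0.20, adjusted p = 0.000595) and 23 in CA1 pyramidal nuclei (0.17, adjusted p = 0.000909). With an estimated correlation the adjusted p was 0.776 in the first 3 and 0.794 in the last. By edgeR, 0 of the 268 single tests of these genes passed, 0 adjusted over the list alone and 14 at an unadjusted p under 0.05, and DESeq2 called 0. Mitochondrial genes made 0.156% ± 0.0578 of UMIs in tau and 0.0959% ± 0.0328 in GFP, and ribosomal protein genes 0.348% ± 0.0766 and 0.309% ± 0.0380 (SD, n = 6). The list of astrocyte homeostasis, with glutamate uptake and gap junction genes, fell in the astrocyte class (median -0.20, 2 of 15 members higher, camera adjusted p = 0.00263; adjusted p = 0.352 with an estimated correlation). By edgeR 0 of its 15 members passed over all genes, 8 stood at an unadjusted p under 0.05, 7 passed adjusted over the list alone and DESeq2 called 1. Without single libraries the 5 list calls became 9 (GFP F1), 8 (GFP F2), 17 (GFP F3), 8 (GFP M1), 12 (GFP M3), 10 (tau F3), 11 (tau M2) or 9 (early enrichment F2).

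In all, edgeR called 235 gene-by-class tests between tau and GFP among 117383, 171 higher and 64 lower in tau. They were 155 higher and 33 lower in astrocytes, 11 and 24 in CA1, 4 and 4 in dentate granule, and 1 and 3 in CA2 and CA3 nuclei. In the other 7 classes edgeR called 0 genes, 4486 stood at an unadjusted p under 0.05 and DESeq2 called 26. The split was 243 higher and 45 lower without the TMM scaling, and 226 and 231 with DESeq2. With classes by marker sum the count was 1. The count fell to 79 without tau M1, 101 without GFP M2, 109 without tau F2 and 128 without tau M2, and rose to 548 without tau M3. Without the 5 libraries of unusual make-up, chosen after the data were seen, 13 calls were left, and Fa2h, Cntn2 and Bin1 stood at adjusted p = 0.0694, 0.0651 and 0.0501. Their log2 fold changes in that fit were 2.67, 2.03 and 0.94. Bin1 stood at adjusted p = 0.113 without tau M1 and 0.0513 without GFP M2. With marked doublets kept, the log2 fold changes of Fa2h, Cntn2 and Bin1 were 0.65 ± 0.21, 0.60 ± 0.20 and 0.24 ± 0.10 (SE, adjusted p = 0.108, 0.139 and 0.225).

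**Figure D2:**
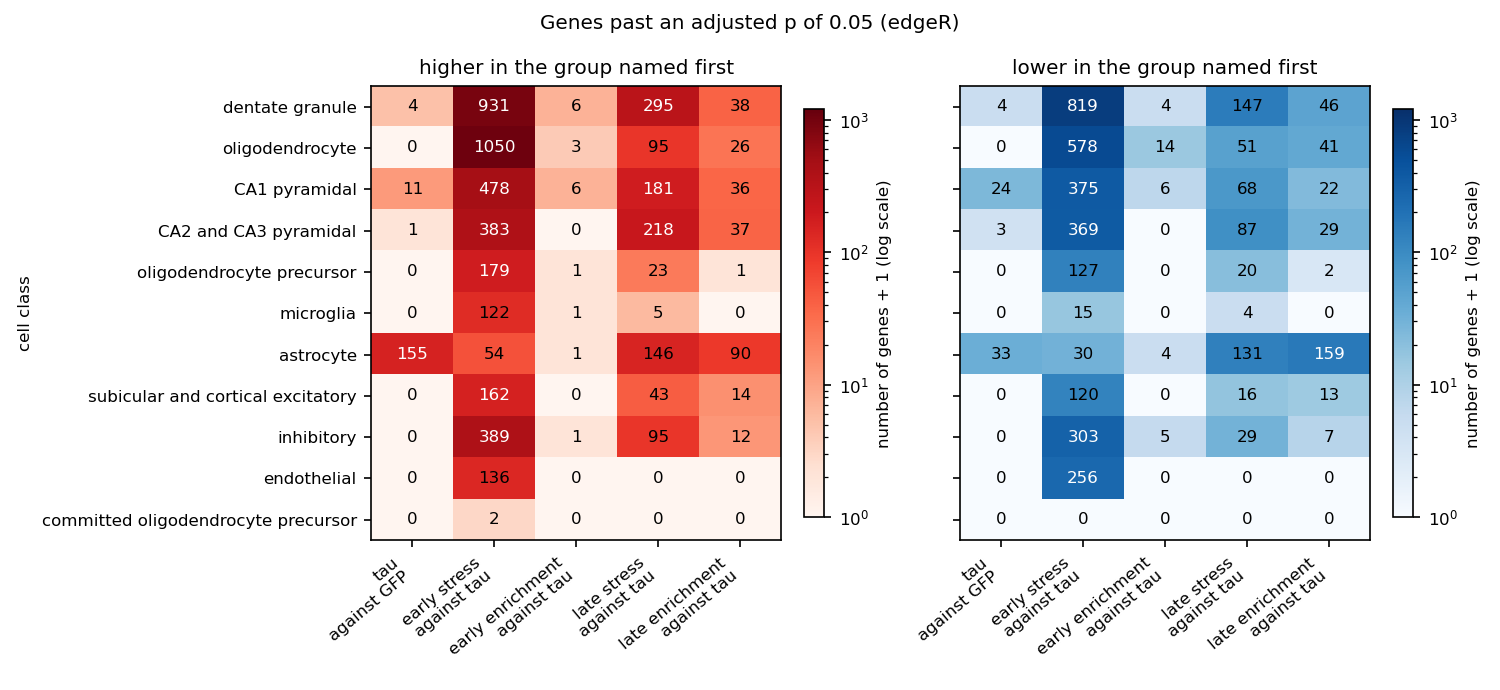
Number of genes past an adjusted p of 0.05 (edgeR, colour on a log scale of the number plus 1) in each cell class (vertical axis) for the 5 comparisons with tau or GFP (horizontal axis), with higher genes in red and lower genes in blue. Early stress against tau has 1050 higher and 578 lower genes in oligodendrocytes, and tau against GFP has 155 higher and 33 lower genes in astrocytes.

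Early stress was compared with tau to ask what early stress added to the tau virus. Hspa8 was higher in dentate granule nuclei and in oligodendrocytes. Hspa8 (ENSRNOG00000034066), the constitutive heat shock 70 chaperone, stood at 129 ± 32.6 CPM (SD, n = 6) in early stress and 62.6 ± 12.0 in tau in dentate granule nuclei, and at 365 ± 91.4 and 168 ± 31.9 in oligodendrocytes. Its log2 fold changes were 1.07 ± 0.13 and 1.11 ± 0.15 (SE, edgeR adjusted p = 2.41e-05 and 3.81e-05, higher in 6 of 6 animals). Hsp90aa1, a heat shock 90 chaperone, rose by 1.03 ± 0.14 in inhibitory nuclei, Hsph1, a co-chaperone, by 0.77 ± 0.12 in oligodendrocytes, and Calr and Hspa5, chaperones of the endoplasmic reticulum, by 0.75 ± 0.10 in inhibitory and 0.59 ± 0.09 in CA1 pyramidal nuclei. Hspa8, Hsp90aa1 and Calr were among 50 genes called higher in 8 or more classes. For these genes free RNA in the droplets and a library batch stay open, as given below. The extra Hspa8 UMIs per nucleus were 0.336 in dentate granule nuclei and 0.244 in oligodendrocytes. Of the heat shock list, 49 of 149 tests were called higher and 1 lower, and 78 passed adjusted over the list alone. Of the unfolded protein response list, 24 of 137 were called, each higher, and 30 adjusted over the list alone.

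Single genes of oxidative phosphorylation and cholesterol synthesis rose too. Ndufv1, a subunit of respiratory complex I, rose by 0.48 ± 0.09 in dentate granule nuclei and Atp5pb, a subunit of the ATP synthase, by 0.55 ± 0.11 in oligodendrocytes (edgeR adjusted p = 0.000372 and 0.000501). Of the oxidative phosphorylation list, 49 of 268 tests were called, each higher, and 120 adjusted over the list alone. Idi1 and Hmgcs1, enzymes of cholesterol synthesis, rose by 0.64 ± 0.13 and 0.45 ± 0.10 in dentate granule nuclei. DESeq2 gave Hmgcs1 an adjusted p of 0.198. Of the cholesterol list, 7 of 147 tests were called higher and 1 lower, and 8 passed adjusted over the list alone. Neither list passed in any class with an estimated correlation.

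Sst, Npy and Slc32a1, transcripts known from interneurons, were higher in excitatory nuclei, and Sst also in glial nuclei. Sst (ENSRNOG00000001837), the somatostatin of a class of interneurons, stood at 16.8 ± 7.80 CPM (SD, n = 6) in early stress and 4.56 ± 1.53 in tau in CA1 pyramidal nuclei, a log2 fold change of 1.85 ± 0.27 (SE, edgeR adjusted p = 6.51e-05). It stood at 90.5 ± 22.5 CPM in endothelial nuclei of early stress, and at 11.0 ± 8.20 in those of late stress. The extra Sst UMIs per nucleus of early stress over tau were 0.0811 in CA1 nuclei, 0.0700 in oligodendrocytes and 0.0776 in microglia. They were 0.152 in inhibitory nuclei. The rise of Sst was thus not particular to excitatory nuclei. Sst and Rab3a were also among the 50 genes called higher in 8 or more classes. Npy, neuropeptide Y, rose by 2.14 ± 0.40 in CA2 and CA3 pyramidal nuclei, Slc32a1, the vesicular GABA transporter of inhibitory neurons, by 1.12 ± 0.23 in dentate granule nuclei, and Bdnf, a neurotrophin, by 0.41 ± 0.09 there. Scg2, a secretory granule protein, rose by 0.51 ± 0.09 in inhibitory nuclei. Of the neurotrophic and neuropeptide list, 22 of 83 tests were called, each higher, and 32 adjusted over the list alone. Rab3a of synaptic vesicles rose by 0.63 ± 0.10, Tubb3, a neuronal tubulin, by 0.60 ± 0.08 and the immediate early gene Jun by 0.47 ± 0.10 in dentate granule nuclei. Grin1, the common NMDA receptor subunit, fell by 0.40 ± 0.07 in CA2 and CA3 nuclei, 1 of 6 calls among 150 tests of the glutamate receptor list, each lower, with 6 adjusted over the list alone. Of the immediate early list 11 tests were called higher and 1 lower of 100, of the synaptic vesicle list 14 and 1 of 100, and of the GABA list 15 and 0 of 98. Adjusted over the list alone, 14, 21 and 18 passed.

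Endothelial nuclei of early stress had less B2m, Bst2, Myl9 and Ccl19 transcript. B2m (ENSRNOG00000017123), the light chain of class I MHC, stood at 477 ± 133 CPM (SD, n = 6) against 1725 ± 663 in tau, a log2 fold change of -1.88 ± 0.38 (SE, edgeR adjusted p = 0.0036, lower in 6 of 6 animals). Bst2, an interferon-induced antiviral protein, fell by 3.23 ± 0.69, Myl9, a myosin light chain of smooth muscle and pericytes, by 2.92 ± 0.52, and Ccl19, a chemokine, by 3.23 ± 0.74. The endothelial class also held markers of pericytes and smooth muscle, and the share of these cells in it was not measured. Assigning classes by marker sum ended the calls of B2m, Bst2 and Myl9 (adjusted p = 0.0522, 0.1 and 0.117). Their log2 fold changes stayed large there, at -2.29, -3.21 and -2.92. Of the MHC list, 9 of 61 tests over the classes were called, each lower, and 14 adjusted over the list alone. Of the interferon list, 6 of 94 were called higher and 1 lower, and 13 adjusted over the list alone. The fixed neuronal markers made 0.512% ± 0.0852 of endothelial UMIs in early stress and 0.395% ± 0.0653 in tau (SD, n = 6, exact permutation p = 0.013), and in oligodendrocytes 1.03% ± 0.0581 and 1.05% ± 0.0434 (exact p = 0.578). In endothelial nuclei the oligodendrocyte markers had a median log2 fold change of 0.887 and the neuronal markers of 0.478. Ribosomal protein genes had -0.919 there, with 1 called higher and 21 lower of 68, and medians of 0.123 to 0.508 in the other 10 classes. Mapt rose by 0.92 ± 0.26 in endothelial nuclei (adjusted p = 0.0234), a call that ended without early stress F2, M1 or M3, tau F1 or tau M3 (adjusted p = 0.0560, 0.0711, 0.0817, 0.0551 and 0.0568). In dentate granule nuclei Mapt had a log2 fold change of 0.04 ± 0.05 (adjusted p = 0.692).

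As lists, heat shock rose in 10 of 11 classes (median log2 fold changes 0.17 to 0.78, smallest camera adjusted p = 2.27e-08), oxidative phosphorylation in 10 (0.25 to 0.52, 2.09e-08), the unfolded protein response in 7 (0.14 to 0.31, 1.45e-05) and the neurotrophic and neuropeptide list in all 5 neuronal classes (0.30 to 0.38, 7.77e-05). With an estimated correlation heat shock passed in 3 classes and the neuropeptide list in 4, each with a smallest adjusted p of 0.00750. The smallest adjusted p with an estimated correlation was 0.151 for oxidative phosphorylation and 0.0702 for the unfolded protein response. In endothelial nuclei the interferon list fell (median -0.70, 0 of 10 members higher, adjusted p = 0.000117) and so did the MHC list (median -1.08, 2 of 8 higher, adjusted p = 0.00093), with adjusted p = 0.209 and 0.177 with an estimated correlation. The reactive astrocyte list fell in astrocytes (median -0.49, adjusted p = 0.0115; 0.20 with an estimated correlation). Cholesterol synthesis rose in astrocytes and subicular and cortical nuclei, GABA signalling in dentate granule and inhibitory nuclei, synaptic vesicle genes in dentate granule and immediate early genes in CA2 and CA3 nuclei (smallest adjusted p = 0.0140, 0.0246, 0.0117 and 0.0282). Their smallest adjusted p with an estimated correlation was 0.240, 0.240, 0.168 and 0.457.

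edgeR called 6878 gene-by-class tests between early stress and tau, 3886 higher and 2992 lower. The counts were 931 and 819 in dentate granule nuclei, 1050 and 578 in oligodendrocytes, 478 and 375 in CA1, 383 and 369 in CA2 and CA3, and 389 and 303 in inhibitory nuclei. Astrocytes had 54 and 30, microglia 122 and 15, and endothelial nuclei 136 and 256. Ribosomal protein genes made 0.409% ± 0.0894 of UMIs in early stress and 0.348% ± 0.0766 in tau, and mitochondrial genes 0.203% ± 0.0995 and 0.156% ± 0.0578 (SD, n = 6). Of the named calls the largest fold was that of ENSRNOG00000054404, which has no symbol, with 0 CPM in oligodendrocytes of all 6 early stress libraries and 43.9 ± 14.4 (SD, n = 6) in tau (edgeR adjusted p = 8.15e-16). With only the 12 libraries of these groups in the fit 3762 tests were called, and with nuclei of at least 1000 genes 4398.

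**Figure D3:**
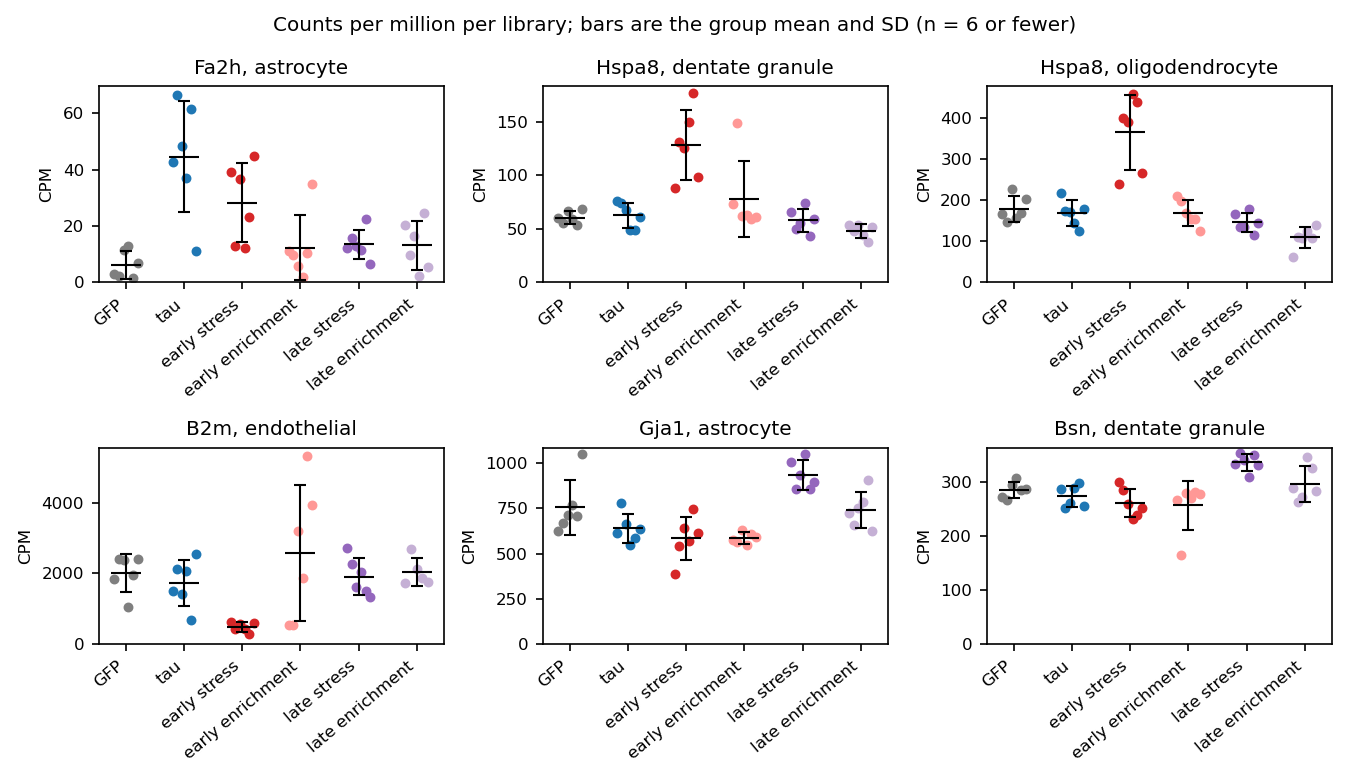
CPM (vertical axis) of Fa2h, Hspa8, B2m, Gja1 and Bsn in 1 or 2 cell classes (panels) in each library, by group (horizontal axis), with the group mean and SD. Hspa8 has a mean of 365 CPM in oligodendrocytes of early stress and 168 in those of tau.

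**Figure D4:**
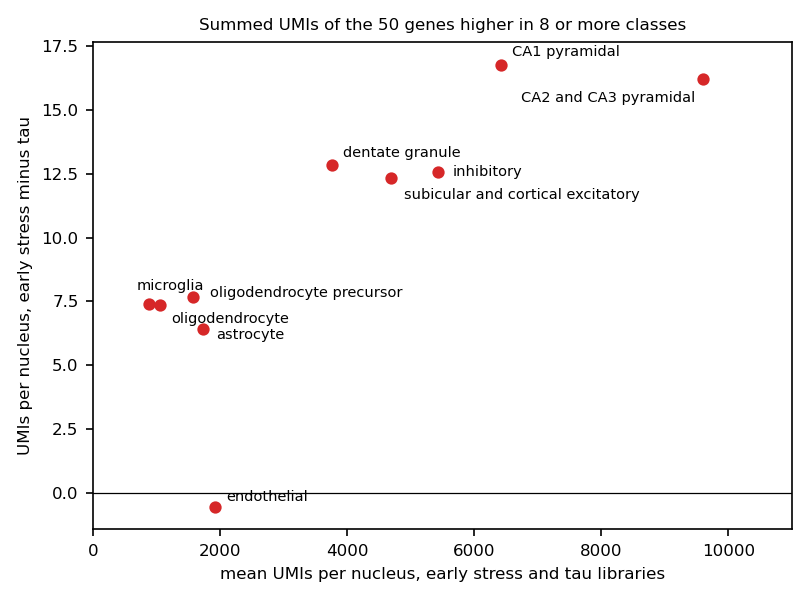
Difference in UMIs per nucleus between early stress and tau (vertical axis), summed over 50 genes called higher in 8 or more classes, against the mean UMIs per nucleus of the class (horizontal axis). The difference is 7.37 UMIs in oligodendrocytes, 12.8 in dentate granule nuclei and -0.558 in endothelial nuclei, where 33 of the 50 genes had more.

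**Figure D5:**
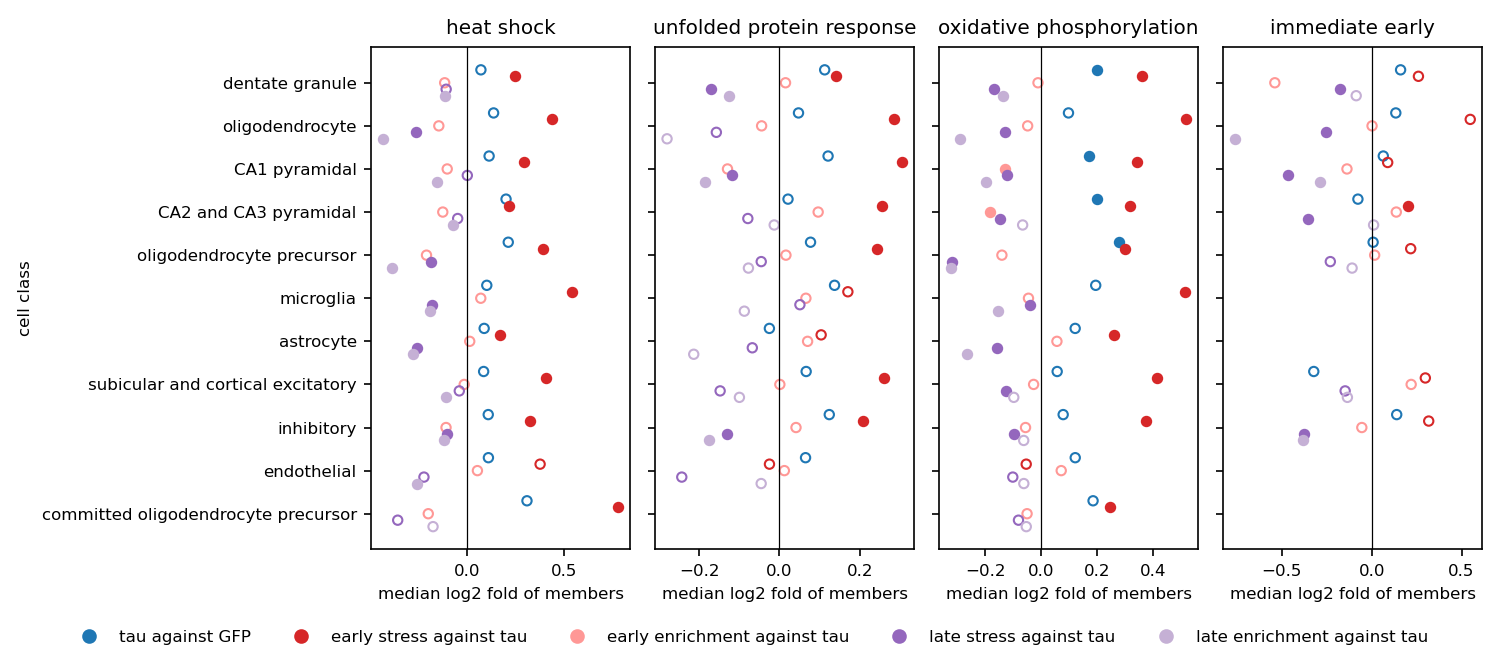
Median log2 fold change of the members (horizontal axis) of 4 gene lists (panels) in each cell class (vertical axis) for the 5 comparisons with tau or GFP (colour). Filled points passed an adjusted p of 0.05 by camera with the preset correlation. The heat shock list passed as higher in 10 classes in early stress and as lower in 10 classes in late enrichment, of which 3 and 0 passed with an estimated correlation.

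Early enrichment was compared with tau to ask what an enriched environment at the early time added. Few genes passed. Tmtc4 (ENSRNOG00000014310), a membrane protein of the endoplasmic reticulum, stood at 91.7 ± 8.40 CPM (SD, n = 5) in early enrichment and 38.0 ± 3.20 (n = 6) in tau in CA1 pyramidal nuclei, a log2 fold change of 1.28 ± 0.13 (SE, edgeR adjusted p = 1.85e-06, higher in 5 of 5 animals). Ngef, a guanine nucleotide exchange factor of neurons, rose by 1.45 ± 0.24 in astrocytes (adjusted p = 0.00123). Nlrc5 (ENSRNOG00000048222), an activator of class I MHC genes, stood at 2.69 ± 2.78 CPM in early enrichment and 18.6 ± 12.0 in tau in oligodendrocytes, a log2 fold change of -3.26 ± 0.49 (adjusted p = 0.000804). With classes by marker sum it was -2.70 (adjusted p = 0.161), and that of Tmtc4 was 1.04 (adjusted p = 0.146). Nlrc5 was the 1 call among the 61 tests of the MHC list, where 4 passed adjusted over the list alone. Oxidative phosphorylation fell in CA2 and CA3 (median log2 fold change -0.18, 4 of 26 members higher, camera adjusted p = 0.00577) and CA1 nuclei (-0.13, 2 of 26, adjusted p = 0.0217), with adjusted p = 0.963 in both with an estimated correlation. By edgeR 0 of its 268 single tests passed, 1 adjusted over the list alone and 11 at an unadjusted p under 0.05, and DESeq2 called 0. Mitochondrial genes made 0.136% ± 0.0429 of UMIs in early enrichment and ribosomal protein genes 0.341% ± 0.0364 (SD, n = 6).

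edgeR called 52 tests between early enrichment and tau, 19 higher and 33 lower, and 8937 of the 117383 stood at an unadjusted p under 0.05. Mapt had a log2 fold change of 0.02 ± 0.06 in dentate granule nuclei (adjusted p = 0.955). The count became 32 without early enrichment M1, 34 without M2, 31 without tau F2, 26 without tau F3, 30 without tau M1 and 198 without tau M3, and 31 without the 5 libraries of unusual make-up, where Ngef stood at adjusted p = 0.0673 (0.143 with nuclei of at least 1000 genes). The 2 list calls became 10 without early enrichment F2, 0 without F3, 8 without M2, 1 without M3, 4 without tau F1, 1 without tau M1 and 7 without tau M2.

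Late stress was compared with tau to ask the same of stress at the late time. Astrocytes of late stress had more Gja1 and Slc1a2 transcript than those of tau. Gja1 (ENSRNOG00000000805), the gap junction protein connexin 43, stood at 934 ± 81.4 CPM (SD, n = 6) in late stress and 639 ± 79.2 in tau, a log2 fold change of 0.55 ± 0.10 (SE, edgeR adjusted p = 0.00106, higher in 6 of 6 animals). Slc1a2, the main glutamate transporter, rose by 0.34 ± 0.07 (adjusted p = 0.0036). Of the 15 members of the astrocyte homeostasis list 4 were called, each higher, and 6 adjusted over the list alone. Cntn2 fell by 2.10 ± 0.42 and Bin1 by 0.80 ± 0.19 in the same class (adjusted p = 0.00238 and 0.0146; 0.0939 for Bin1 without tau M1). The oligodendrocyte markers made 0.0761% ± 0.0283 of astrocyte UMIs in late stress against 0.174% ± 0.0653 in tau (SD, n = 6, exact permutation p = 0.00433, adjusted p = 0.0108). In GFP they made 0.0779% ± 0.0162. The same 6 tau libraries served in tau against GFP. A departure of the tau group alone therefore cannot be told apart from an effect of late stress here.

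In neurons of late stress Bsn was higher in dentate granule, CA2 and CA3 and CA1 nuclei. Bsn (ENSRNOG00000030714), the active zone scaffold bassoon, stood at 337 ± 16.1 CPM (SD, n = 6) in late stress and 274 ± 19.6 in tau in dentate granule nuclei, a log2 fold change of 0.30 ± 0.06 (SE, edgeR adjusted p = 0.00139), and rose by 0.35 ± 0.05 in CA2 and CA3 and 0.31 ± 0.07 in CA1 nuclei. Sv2a, a synaptic vesicle protein, rose by 0.31 ± 0.07 in dentate granule nuclei. Of the synaptic vesicle list 6 of 100 tests were called higher and 2 lower, and 18 passed adjusted over the list alone. Vgf, a neurosecretory protein, fell by 0.90 ± 0.19 and Hspa5 by 0.42 ± 0.10 in dentate granule nuclei, and Cryab, a small heat shock protein, by 1.83 ± 0.36 in CA2 and CA3 nuclei. DESeq2 gave Hspa5 an adjusted p of 0.11. With classes by marker sum Vgf, Hspa5 and Cryab fell by 0.76, 0.32 and 0.86 (adjusted p = 0.187, 0.147 and 0.182). In oligodendrocytes Plcg2, a phospholipase of immune receptor signalling, rose by 2.42 ± 0.26 and Sema5b, a semaphorin, by 3.09 ± 0.50. Sema5b rose in oligodendrocytes of late enrichment too, by 2.67 ± 0.62 (edgeR adjusted p = 0.0372). Nek5, a kinase, rose by 3.19 ± 0.65 in CA1 and 3.33 ± 0.67 in inhibitory nuclei.

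The immediate early list fell in 5 classes in late stress, most in CA1 nuclei (median log2 fold change -0.47, 0 of 17 members higher, camera adjusted p = 1.57e-05; 0.367 with an estimated correlation). Its single tests had 3 calls among 100, each lower, and 9 adjusted over the list alone. Oxidative phosphorylation fell in 9 classes (medians -0.32 to -0.04, smallest adjusted p = 2.44e-05; 0.471 with an estimated correlation), with 2 of 268 single tests called, both lower, and 0 adjusted over the list alone. Mitochondrial genes made 0.126% ± 0.0349 of UMIs in late stress and 0.156% ± 0.0578 in tau, and ribosomal protein genes 0.323% ± 0.0528 and 0.348% ± 0.0766 (SD, n = 6). Heat shock fell in 5 classes (medians -0.27 to -0.10, smallest adjusted p = 0.000166; 0.367), with 5 of 149 called lower and 11 adjusted over the list alone, and the unfolded protein response in 3 (-0.17 to -0.12, 0.00396; 0.254), with 5 of 137 and 7. The neuropeptide list fell in CA1 and dentate granule nuclei (adjusted p = 0.00491 and 0.0379; 0.254 in both with an estimated correlation), the immature neuron list in dentate granule nuclei (0.0119; 0.471) and the list of tau and its kinases in subicular and cortical nuclei (0.00685; 0.254). Astrocyte homeostasis rose (median 0.24, 13 of 15 members higher, adjusted p = 8.74e-05; 0.0987 with an estimated correlation).

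edgeR called 1654 tests between late stress and tau, 1101 higher and 553 lower, with 295 and 147 in dentate granule, 218 and 87 in CA2 and CA3, 181 and 68 in CA1 and 95 and 51 in oligodendrocyte nuclei, and 146 and 131 in astrocytes. The split was 711 and 766 without the TMM scaling, which moved 1 class by over 0.1 on the log2 scale, at -0.12. Mapt had a log2 fold change of 0.06 ± 0.05 in dentate granule nuclei (adjusted p = 0.641). The count fell to 1037 without late stress F2, 949 without F3, 918 without M2 and 1074 without tau F2. The 27 list calls fell to 12 without late stress F2, 17 without M3 and 16 without tau M3. With doublets kept the log2 fold changes of Cntn2 and Bin1 were -0.48 ± 0.20 and -0.27 ± 0.10 (SE, edgeR adjusted p = 0.191 and 0.107), and with only the 12 libraries of these groups Nek5 stood at adjusted p = 0.0686 in CA1 nuclei.

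Late enrichment was compared with tau to ask the same of enrichment at the late time. In astrocytes Slc6a11 (ENSRNOG00000005697), a GABA transporter of glia, stood at 185 ± 27.0 CPM (SD, n = 6) in late enrichment and 123 ± 24.3 in tau, a log2 fold change of 0.55 ± 0.13 (SE, edgeR adjusted p = 0.0129, higher in 6 of 6 animals; 0.0641 without late enrichment F3). Slc1a2 rose by 0.30 ± 0.07 and Stab2, a scavenger receptor, by 3.41 ± 0.68 (adjusted p = 0.013 and 0.00245). Of the 15 astrocyte homeostasis genes 4 were called, each higher, and 5 adjusted over the list alone. Bin1 fell by 1.02 ± 0.21 and Atp5f1b, an ATP synthase subunit, by 0.57 ± 0.13 (adjusted p = 0.00439 and 0.00855). The oligodendrocyte markers made 0.0919% ± 0.0495 of astrocyte UMIs against 0.174% ± 0.0653 in tau (SD, n = 6, exact permutation p = 0.0281, adjusted p = 0.0469). The 6 tau libraries were again the same, so a departure of the tau group cannot be told apart from an effect of late enrichment. In CA1 nuclei Nek5 (ENSRNOG00000048769) stood at 9.94 ± 1.09 CPM in late enrichment and 0.671 ± 0.516 in tau, a log2 fold change of 3.83 ± 0.60 (adjusted p = 0.00222). The transcript ENSRNOG00000062930, which has no symbol, fell by 2.12 ± 0.30 in CA1 and 2.13 ± 0.30 in dentate granule nuclei. In late stress it fell by 1.80 ± 0.29 in dentate granule nuclei, and Stab2 rose by 3.06 ± 0.69 in astrocytes (edgeR adjusted p = 0.000584 and 0.006). The adjusted p of the former was 0.056 with only the 12 libraries compared, and that of Stab2 was 0.0728 with classes by marker sum.

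Heat shock fell in 10 of 11 classes in late enrichment (median log2 fold changes -0.44 to -0.08, smallest camera adjusted p = 0.00093; 0.28 with an estimated correlation), with 3 of 149 single tests called, each lower, and 12 adjusted over the list alone. Oxidative phosphorylation fell in 6 classes (medians -0.32 to -0.14, 0.00041; 0.420), with 2 of 268 called lower and 4 adjusted over the list alone. Mitochondrial genes made 0.1005% ± 0.0168 of UMIs in late enrichment and 0.156% ± 0.0578 in tau, and ribosomal protein genes 0.308% ± 0.0308 and 0.348% ± 0.0766 (SD, n = 6). The unfolded protein response fell in 3 classes (smallest adjusted p = 0.00159; 0.145 with an estimated correlation), immediate early genes in 3 (0.00041; 0.145), the neuropeptide list in 3 (0.000846; 0.145), the circadian clock list in 2 (0.0426; 0.28), and the MHC list in dentate granule nuclei (0.04; 0.182). The list of tau and its kinases fell in subicular and cortical nuclei (median -0.10, 5 of 23 members higher, adjusted p = 0.00353; 0.145), with 4 of 234 single tests called, each lower, and 4 adjusted over the list alone. Cholesterol synthesis rose in CA1 nuclei (median 0.13, 0.0426; 0.389) and astrocyte homeostasis in astrocytes (median 0.16, 11 of 15 members higher, 0.0157; 0.28).

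edgeR called 573 tests between late enrichment and tau, 254 higher and 319 lower, with 90 and 159 in astrocytes and 38 and 46 in dentate granule nuclei. The split was 162 and 360 without the TMM scaling, which moved 1 class by over 0.1 on the log2 scale, at -0.11. Mapt had a log2 fold change of 0.07 ± 0.05 in dentate granule nuclei (adjusted p = 0.642). The count fell to 188 without late enrichment F2, 181 without F3, 260 without M1, 351 without M2, 368 without tau F1, 256 without tau F2 and 311 without tau M1. It was 366 without the 5 libraries of unusual make-up, where Slc6a11, Slc1a2 and Bin1 stood at adjusted p = 0.0627, 0.0541 and 0.0917. Their log2 fold changes in that fit were 0.55, 0.31 and -0.73. With nuclei of at least 1000 genes Slc6a11 and Bin1 stood at 0.169 and 0.0755, and with doublets kept Atp5f1b fell by 0.27 (adjusted p = 0.236) and Bin1 by 0.37 (adjusted p = 0.0376). The 31 list calls fell to 20 without late enrichment F2, 13 without F3, 20 without tau F1 and 16 without tau M3.

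Of the 23 lists, 8 had no camera call in the 5 comparisons with tau or GFP: glucocorticoid responsive, noradrenergic, glutamate receptors and postsynaptic density, disease associated microglia, homeostatic microglia, complement, myelin, and disease associated oligodendrocyte genes. Of their 145 list tests 0 passed, 9 stood at an unadjusted p under 0.05 and fry called 1. Their smallest adjusted p was 0.0517, for glutamate receptors, and 0.061 for disease associated oligodendrocyte genes.

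Stress and enrichment were also compared directly at each time. Between early stress and early enrichment edgeR called 11817 tests, 7118 higher and 4699 lower in early stress. In oligodendrocytes Sema5b (ENSRNOG00000002238) stood at 27.9 ± 5.88 CPM (SD, n = 6) in early stress and 1.79 ± 0.786 in early enrichment, a log2 fold change of 3.86 ± 0.45 (SE, edgeR adjusted p = 5.28e-07). ENSRNOG00000054404 stood at 0 there and at 42.6 ± 17.6 CPM in early enrichment (adjusted p = 1.11e-15), and AABR07016623.1 at 0 and 27.2 ± 9.87 CPM in microglia (adjusted p = 0.000256). In endothelial nuclei Psmb9, a subunit of the immunoproteasome, fell by 4.25 ± 0.91 (adjusted p = 0.00249). Heat shock and oxidative phosphorylation genes were each higher in 10 classes (smallest camera adjusted p = 1.03e-11 and 8.27e-12), of which 6 and 0 passed with an estimated correlation (smallest adjusted p = 0.0126 and 0.0722). Mitochondrial genes made 0.203% ± 0.0995 of UMIs in early stress and 0.136% ± 0.0429 in early enrichment, and ribosomal protein genes 0.409% ± 0.0894 and 0.341% ± 0.0364 (SD, n = 6). In the subicular and cortical class, with 656 higher and 587 lower genes, cluster 8 held 51.7% of the nuclei of early stress and cluster 7 held 55.9% of those of early enrichment. Without early enrichment F3 the count was 6780.

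Between late stress and late enrichment edgeR called 113 tests, 97 higher and 16 lower in late stress. In CA1 nuclei Tex22 (ENSRNOG00000028158), a gene first known from testis, stood at 36.1 ± 4.23 CPM (SD, n = 6) in late stress and 18.1 ± 10.2 in late enrichment, a log2 fold change of 1.14 ± 0.16 (SE, edgeR adjusted p = 0.000523). G6pc3, a glucose-6-phosphatase, fell by 0.65 ± 0.11 in subicular and cortical and 0.55 ± 0.09 in inhibitory nuclei (adjusted p = 0.00134 and 0.00286). The count became 34 without late enrichment F2, 44 without F3, 40 without M3, 70 without late stress F1, 68 without F3 and 61 without M1. It was 29 with sex as an additive covariate, 25 with a replicate block, 10 with that block and the median UMI count, and 485 with classes by marker sum. Tex22 in CA1 nuclei stood at adjusted p = 0.0884 with additive sex, 0.127 with block and median UMI count, and 0.119 with only the 12 libraries of these groups.

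Between late and early stress edgeR called 20197 tests, 8771 higher and 11426 lower in late stress. Heat shock genes fell in all 11 classes (median log2 fold changes -1.19 to -0.31, smallest camera adjusted p = 3.37e-10), and 10 passed with an estimated correlation. Mitochondrial genes made 0.126% ± 0.0349 of UMIs in late stress and 0.203% ± 0.0995 in early stress, and ribosomal protein genes 0.323% ± 0.0528 and 0.409% ± 0.0894 (SD, n = 6). With the ribosomal share as a covariate 12150 tests were called. In endothelial nuclei Psmb9 (ENSRNOG00000000459) stood at 65.1 ± 44.9 CPM (SD, n = 6) in late stress and 7.14 ± 11.9 in early stress, a log2 fold change of 4.20 ± 0.91 (SE, edgeR adjusted p = 0.00286), and Sst fell by 3.17 ± 0.53 (adjusted p = 8.99e-05). In oligodendrocytes of late stress ENSRNOG00000054404 stood at 40.4 ± 7.18 CPM and in microglia AABR07016623.1 at 20.2 ± 14.8, against 0 in early stress (adjusted p = 5.58e-16 and 0.000496). Between late and early enrichment edgeR called 733 tests, 375 higher and 358 lower in late enrichment, and 222 and 381 without the TMM scaling, which moved 1 class by -0.10 on the log2 scale. In dentate granule nuclei ENSRNOG00000062930 stood at 94.3 ± 23.9 CPM (SD, n = 6) in late and 564 ± 168 in early enrichment, a log2 fold change of -2.45 ± 0.31 (adjusted p = 0.000536). That count became 453, 480, 429 and 463 without early enrichment F1, M1, M2 and M3, and 268, 339, 439 and 452 without late enrichment F2, F3, M1 and M2.

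The genes called between tau and GFP were then tested as lists in the direct comparisons, which share no library with tau or GFP. The 155 astrocyte genes higher in tau were also higher in early stress than in early enrichment (median log2 fold change 0.19, 106 members higher, camera adjusted p = 0.0106; 0.933 with an estimated correlation). It was the 1 list test of 8 that passed. In late stress against late enrichment the same 155 genes had a median log2 fold change of -0.02 (adjusted p = 0.746). The list was chosen on libraries of the same series, and its genes are 75.48% genes over 2-fold more abundant in the oligodendrocyte class than in astrocytes.

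Females and males were compared over all 6 groups, with 18 animals of each sex. The females included late stress F3, which had 0.627 CPM of ENSRNOG00000037911, where the other females had 1434 to 2226. That library also entered the sex by treatment tests as a female of late stress. The male-linked genes led the list. In dentate granule nuclei Kdm5d (ENSRNOG00000060496), a histone demethylase of the Y chromosome, stood at 0.122 ± 0.156 CPM (SD, n = 18) in females and 96.6 ± 9.50 in males (edgeR adjusted p = 5.22e-46), and Ddx3 (ENSRNOG00000057231), an RNA helicase gene that the files list under this symbol, at 0.0251 ± 0.0582 and 77.6 ± 8.49 (adjusted p = 1.07e-34). edgeR called 218 tests, 119 higher and 99 lower in females, and 349 without early stress M1.

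Whether the sexes differed in their response was tested as a difference of differences. In early stress against tau 643 gene-by-class tests passed, 266 with a higher and 377 with a lower change in females, and 440 of them lay in dentate granule and 101 in CA1 nuclei. Hras, a small GTPase of growth signalling, differed by -1.51 ± 0.23 on the log2 scale in dentate granule nuclei (SE, edgeR adjusted p = 0.000399). Its levels were 23.6 ± 3.50 CPM (SD, n = 3) in females of early stress and 32.8 ± 2.55 in females of tau, and 38.9 ± 1.60 and 18.5 ± 2.24 in males. Pde10a, a cyclic nucleotide phosphodiesterase, differed by 1.03 ± 0.15 in the same class and 1.10 ± 0.16 in inhibitory nuclei, and Tuba1b, an alpha tubulin, by -0.91 ± 0.14 in dentate granule nuclei and -1.24 ± 0.20 in oligodendrocyte precursors. With nuclei of at least 1000 genes Tuba1b stood at adjusted p = 0.158 in precursors, and with the ribosomal share as a covariate Pde10a stood at 0.0561 in inhibitory nuclei. In tau against GFP 4 tests passed, in early enrichment against tau 18, in late stress against tau 6 and in late enrichment against tau 11, and each of these had from 8332 to 9905 tests at an unadjusted p under 0.05. DESeq2 called 57, 149, 42 and 56 in these, and 604 in early stress. The count over these comparisons, 682, became 226 without early stress F1, 1131 without F3, 1417 without M2, 366, 321 and 306 without tau F2, F3 and M2, and 1106 without tau M3. With the ribosomal share as a covariate it fell below each of these, and with classes by marker sum it rose above them, as given further below.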

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

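The tests of a library batch, of libraries of unusual make-up, of a swap and of another piece of tissue were chosen only after the results were seen, and so were the values with the ribosomal share as a covariate and without 5 libraries.

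Single libraries lay far from the 5 others of their group by Dixon's criterion, which chance meets in about 1 of 20 groups. That held in 10 of 96 groups of library values and in 1 of 41 groups of gene values. The mitochondrial share of GFP M3 was 0.1589% (others 0.0666% to 0.0984%). Of the shares of nuclei, dentate granule nuclei made 18.42% in early stress F1 (others 24.26% to 27.32%), oligodendrocytes 18.04% in early stress M3 (25.97% to 29.18%) and 6.509% in GFP F2 (25.17% to 35.42%), and astrocytes 9.393% in GFP F2 (2.772% to 4.703%). CA1 nuclei made 0.048% in early enrichment F2 (6.098% to 8.497%) and 14.24% in late enrichment F1 (7.827% to 9.583%), and subicular and cortical nuclei 1.169% in early enrichment F2 (7.922% to 9.818%). Oligodendrocyte precursors made 6.605% in early enrichment M3 (4.456% to 5.235%), and endothelial nuclei 1.974% in late enrichment M3 (0.191% to 0.774%). Nlrc5, the activator of class I MHC genes, stood at 41.42 CPM in oligodendrocytes of tau M2 (7.395 to 18.1).

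The sexes differed in their change in 4 gene-by-class tests for tau against GFP, 643 for early stress, 18 for early enrichment, 6 for late stress and 11 for late enrichment, the last 4 against tau, by a test of the difference itself. DESeq2 called 57, 604, 149, 42 and 56. The log2 differences between the sexes were -0.8244 for Nek6 in inhibitory nuclei (tau against GFP), -1.2386 and -0.9096 for Tuba1b in oligodendrocyte precursors and dentate granule nuclei, 1.1022 and 1.0294 for Pde10a in inhibitory and dentate granule nuclei, -1.5061 for Hras in dentate granule nuclei (early stress), 1.4631 for Hdac4 in astrocytes (early enrichment) and -1.1031 for Man1a1 in CA2 and CA3 nuclei (late enrichment). The adjusted p of Nek6 was 0.287, 0.0706 and 0.209 without tau F3, M1 and M2, and 0.0738, 0.0954 and 0.109 without GFP F1, F2 and M1. That of Hdac4 was 0.0688 without early enrichment F2, and that of Man1a1 0.0505 without tau M3 and 0.0546 without late enrichment F2.

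Genes higher in early stress than in tau in 8 or more classes numbered 50, with 432 calls and a median log2 fold change of 0.81. RNA of neurons in other nuclei is argued against as a full account in oligodendrocytes. The fixed neuronal markers outside these genes had a median log2 fold change of 0.1971 there, where the 50 genes had 0.97. These markers still rose (mean 0.33 ± 0.08, SE over markers). Markers among the 50 genes, such as Sst, were left out of the test, which cannot speak for them. In endothelial nuclei the neuronal markers had a median of 0.4782 and the oligodendrocyte markers 0.8866, where the 50 genes had 0.9738. Free RNA of 1 pool in the droplets stays open for the 50 genes as a set. Their extra UMIs per nucleus rose with the UMIs of a class with a median slope of 0.3573 (quartiles 0.2597 to 0.4931). That lies between the values set for a shared pool (under 0.25) and for a change in the nuclei (over 0.75). Single genes lay on both sides, with Sst at 0.1111, as for a shared pool, and Chst1 at 1.1694. In endothelial nuclei, with 1923 UMIs each, the extra UMIs of the 50 genes summed to -0.5584, against 7.387 in microglia with 881, but genes that fell there, such as Actb, enter that sum. A library batch cannot be told apart from the treatment, because all 6 groups hold 6 consecutive library numbers. The transcript ENSRNOG00000054404 stood at 0 CPM in oligodendrocytes of all 6 early stress libraries, and at 21.59 CPM or more in each library of tau, early enrichment and late stress. In microglia AABR07016623.1 stood at 0 CPM in all 6 early stress libraries. It lay at 18.73 to 43.86 CPM in early enrichment and at 0 to 37.05 in late stress. With the ribosomal share as a covariate 73.61% of the 432 calls passed, with a median log2 fold change of 0.6423 in place of 0.8146. Early stress itself stays among the open explanations, untested.

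Oligodendrocyte genes were higher in astrocytes of tau than of GFP: 117 of the 155 genes (75.48%) were over 2-fold more abundant in the oligodendrocyte class, against 8.74% of all tested genes. Oligodendrocyte RNA in the astrocyte class could account for them, since the fixed oligodendrocyte markers rose there with a median log2 fold change of 1.338. The libraries of unusual make-up are argued against as its source, since the median was 1.3556 without them. The astrocyte calls went from 188 to 0 in that fit. With fewer animals the log2 fold change of Fa2h was 2.67 in place of 2.88, and its adjusted p 0.0694. A change of astrocytes by tau stays open, untested.

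The library labelled early enrichment F2 had few dentate granule and pyramidal nuclei. Whether its label was exchanged with that of another library of the series stays open. Such a swap would not alter the nuclei of this library and so could not account for its make-up. No test was made of the share, and 0 other libraries had under 5% dentate granule nuclei, the lowest with 16.532%. An exchange of labels would leave that count as it is, so the count cannot decide whether labels were exchanged. Another piece of tissue could account for it, since 40.341% of its nuclei lay in the unnamed cluster 9, of which other libraries held at most 5.6%, and 52.015% lay in unnamed clusters. No biological explanation was tested.

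Other splits of the same 12 animals, 41 with the real one and each with 3 of each sex on both sides, were tested for each count of calls. For tau against GFP (235 calls, highest other split 162) the real split alone, 1 of the 41, gave as many. So it did for early stress (6878, 2084), late stress (1654, 257) and late enrichment (573, 33) against tau. It also did for early stress against early enrichment (11817, 4868) and late stress against late enrichment (113, 69). The same was seen for late against early stress (20197, 5403) and late against early enrichment (733, 410). With sex regrouped within treatment it held for sex by treatment (682, 148, with 1 of 41). Chance is argued against for these counts in the main fit. A share under 1 of 41 could not be seen, and the shares were not adjusted for the number of counts. Splits were made in the main setting only. In some other settings, given below, tau against GFP, late stress against late enrichment and sex by treatment fell under their highest other split. For females against males (218, 268) 2 of 41 gave as many. The regrouping beside the real one gave more calls than it, so chance is not excluded for that count. Chance cannot be excluded either for early enrichment against tau (52, 67), where 4 of 41 splits gave as many. For list calls the real split alone gave as many for early stress (41, 37) and late enrichment (31, 24), with 1 of 41 splits each. Chance is not excluded for the list calls of tau against GFP (5, 32), early enrichment (2, 20) and late stress (27, 38), with 14, 30 and 4 of 41. The lists of tau against GFP and early enrichment had splits with several times the real count, a sign of some structure among the libraries, of which no source was tested. It cannot be excluded for the tau genes in stress and enrichment (1, 6), where 94 of 100 splits gave as many.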

How the results depend on the processing

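The ribosomal share as a covariate, the fits without 5 libraries of unusual make-up and those without early enrichment F2 outside its own comparisons were chosen only after the results were seen. Of 1518 results of named genes in other settings 1415 kept their direction and their side of the threshold and 102 lost the threshold. Nxph1 in astrocytes of late stress and tau reversed, with a log2 fold change of 0.27 with classes by marker sum. With 1 library left out, 1526 of 1557 kept both and 31 lost the threshold. Counts of calls outside 1.5 times the count given were as follows, and the cause was not tested. Tau against GFP: 102 adjusted over all classes together, 457 with DESeq2, 1 with classes by marker sum, 410 with no expression filter, 142 with a replicate block, 117 with block and median UMI covariate, 13 without the 5 libraries. Early stress against tau: 4398 with at least 1000 genes per nucleus, 3762 with only the 12 libraries compared, 4553 with block and covariate. Early enrichment against tau: 82 with DESeq2, 27 with at least 1000 genes, 21 by marker sum, 90 with doublets kept, 151 with no filter, 31 without the 5 libraries. Late stress against tau: 4493 by marker sum, 3083 with doublets kept. Late enrichment against tau: 376 with at least 1000 genes, 142 by marker sum, 962 with the 12 libraries, 366 without the 5. Early stress against early enrichment: 6799 with at least 1000 genes, 7718 with the 12 libraries. Late stress against late enrichment: 75 adjusted over all classes, 29 with additive sex, 485 by marker sum, 45 with the median UMI covariate, 72 with the 12 libraries, 25 with the block, 10 with block and covariate, 195 with the ribosomal covariate, 29 without the 5. Late against early stress: 12150 with the ribosomal covariate. Late against early enrichment: 1240 with the 12 libraries, 431 with block and covariate. Sex by treatment: 384 adjusted over all classes, 1473 by marker sum, 1297 with no filter, 140 with the ribosomal covariate. List calls of tau against GFP: 13 with doublets kept, 0 with an estimated correlation, 2 with fry, 10 with no filter. Of early stress: 7 with an estimated correlation. Of early enrichment: 10 with doublets kept, 0 with an estimated correlation, 0 with fry, 5 with no filter. Of late stress: 0 with an estimated correlation, 2 with fry. Of late enrichment: 0 with an estimated correlation, 14 with fry. Class shares: 3 with doublets kept. Tau genes under stress and enrichment: 0 with an estimated correlation, 2 with lists at an unadjusted p below 0.001. With 1 library left out the calls ranged from 79 to 548 (tau against GFP), 4649 to 7386 (early stress), 26 to 198 (early enrichment), 918 to 2075 (late stress), 181 to 636 (late enrichment), 6780 to 12224 (early stress against early enrichment), 34 to 155 (late stress against late enrichment), 16066 to 20678 (late against early stress), 268 to 783 (late against early enrichment), 182 to 349 (females against males) and 226 to 1417 (sex by treatment). The list calls ranged from 5 to 17, 36 to 44, 0 to 10, 12 to 32 and 13 to 34 for tau against GFP, early stress, early enrichment, late stress and late enrichment. Libraries with the same replicate number had a mean residual correlation of -0.0127 to 0.0019 over the classes. From 8 of 36 libraries (astrocytes) to 21 of 35 (microglia) were closest to their own number. Whether a number stands for more than a label stays open, and the replicate block rests on these numbers. With that block the other calls were 4762 (early stress), 61 (early enrichment), 1538 (late stress), 540 (late enrichment), 10698 (early stress against early enrichment), 18466 (late against early stress) and 506 (late against early enrichment). The list calls with it were 5, 43, 2, 26 and 29, with 0 class shares (smallest possible exact p 0.0313) and 1 test of tau genes. It ended the calls of Cdh10 (adjusted p = 0.158), Tmtc4 (0.071) and Nfkbia (0.0626), and of Pdilt in tau against GFP (0.239) and late enrichment (0.0682). Classes by marker sum ended calls in astrocytes, with adjusted p and log2 fold change as follows: Fa2h (0.0708, 1.54), Cntn2 (0.178, 1.26) and Bin1 (0.159, 0.51) in tau against GFP, Ngef (0.434, 0.80) in early enrichment, Gja1 (0.0641, 0.69), Slc1a2 (0.109, 0.52), Cntn2 (0.151, -1.21) and Bin1 (0.0661, -0.63) in late stress, and Slc6a11 (0.110, 0.64), Slc1a2 (0.266, 0.43), Bin1 (0.0614, -0.72) and Atp5f1b (0.332, -0.33) in late enrichment. It also ended those of Mapt in endothelial nuclei (0.271, 0.43), and of the sex differences of Nek6 (0.290, -0.73), Hdac4 (0.196, 1.03) and Man1a1 (0.575, -0.76). Nek6 was also lost over all classes together (0.0887), without TMM (0.0623), with the ribosomal covariate (0.422) and without the 5 libraries (0.118), and Hdac4 with at least 1000 genes (0.170) and without the 5 (0.135). Bin1 in tau against GFP was lost over all classes together (0.0599) and with only the 12 libraries (0.0881), and Hspa5 in late stress with block and covariate (0.0565).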

Other observations

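The test of a male animal was chosen only after the result was seen.

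In the library labelled late stress F3, a female, the transcript ENSRNOG00000037911 had 16 UMIs (0.627 CPM), where the other libraries labelled female had 1434 to 2226 CPM. The transcript ENSRNOG00000065796 had 0 UMIs in it, against 137 to 234.6 CPM in the other females. A male animal is argued against, since Kdm5d stood at 0.12 CPM over its nuclei, where the lowest library labelled male had 61.9 and the other females had at most 0.299. A single X chromosome could account for the 2 low transcripts and stays open. Of 49 genes higher in females, called without this library, 51.02% lay nearer to the male mean in it. The other females had 6.12% to 26.53% and males 59.18% to 89.8%. Of 53 genes higher in males, 66.04% lay nearer to the male mean, against 11.32% to 49.06% in the other females and 62.26% to 96.23% in males.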
